A study of Mus musculus with 18 samples.

How the data were processed

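Poly(A)-selected RNA of about 30 mg of frozen lung per sample was sequenced from 18 libraries in 6 groups of 3, and libraries were made from 1 µg of input with a kit that does not mark strand, per the labels' protocols. Fragments of a gene and of an overlapping antisense gene can therefore not be told apart. Reads were checked with FastQC, aligned with TopHat and quantified with Cuffdiff on mm10, per the submitters' processing notes; versions and the gene annotation are not given in the sources used here. The authors deposited estimated counts of fragments per gene and library, not normalized, in which 93.3% of values were whole. The other values may come from splitting a fragment shared between genes, which was not tested. The authors also deposited FPKM values, scaled across libraries, and a table of Cuffdiff comparisons of 15 pairs of conditions, from which the p-value, the q-value and the sign of the test score were used. Replicate libraries were kept apart by the authors, per the file headers.

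Of 23356 features, 5 with the Cuffdiff status HIDATA, which puts 0 in place of an estimate, were left out, and 20 with the status FAIL in some library were kept. Symbols of 25 genes had turned into dates in the deposited table and are shown as such. Coordinates are those of the deposited table on mm10, and 21522 symbols were matched to a RefSeq table of the same assembly, where 49.0% of starts were equal after adding 1.

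Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr over the 6 groups (15387 genes kept), 1 fit of all 18 libraries and quasi-likelihood F-tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p for a gene is from this test unless another is named, log2 changes are given with SE, and CPM with SD over 3 libraries. Contrasts were hypoxia against normoxia in each genotype, each of the other 2 lines against wild type in each exposure, and the differences of hypoxia responses. Alternatives were DESeq2 1.42.0, DESeq2's size factors in edgeR, no filter, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1) with an FPKM minimum of 1 in 3 libraries or none, only the groups compared, the replicate number as a block, haemoglobin genes left out, and each library left out in turn. Fits without the 2 libraries of lowest total and with a tissue score as covariate were chosen after seeing the data.

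Gene lists of pathways and cell types, the contrasts, the tests and the rule for named genes were set before the data were examined. The rule names both arrestin genes; in each contrast the 5 highest and 5 lowest log2 changes among called genes with a mean log2 CPM of at least 1 whose groups do not overlap (no such condition for interactions), leaving out unnamed gene models; up to 4 called members of each list; the 5 smallest p where nothing was called; and called genes near the targeted gene. Not every gene the rule names is shown, and Hmgn2 and Hdac1 were also looked up in the other line after their values were seen. List members were dropped for length, first those whose calls were lost when a library was left out. Lists of at least 5 measured genes (38) were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Of the preset calls, the pericyte list in wild type hypoxia held with the estimated correlation and the others did not. A floor of 3 fragments over the group was used where a group had 0. Counting intervals and floors cover counting error only.

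The tests were tested on simulated counts with wild type hypoxia against wild type normoxia as a model and 15387 genes: edgeR called 43.3% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 97.0% of those changed 4-fold, with 6.7% false calls among calls, and DESeq2 had 13.8% false calls. Camera called 0 of 30 unchanged lists. The simulated genes varied independently, so this does not show how camera treats lists whose members vary together. In the real data the estimated correlation of the cardiac muscle list was 0.812, far above the preset. Figures were drawn with matplotlib 3.10.9.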

Results

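RNA of whole lung was sequenced from male mice of 3 genotypes: wild type, lacking β-arrestin 1 (β-arrestin 1 −/−) and labelled as lacking β-arrestin 2 (β-arrestin 2 −/−). β-Arrestins are adaptor proteins that bind activated G protein-coupled receptors, end their coupling to G proteins and link them to other signalling proteins. Mice entered the experiment at 8 to 12 weeks of age and were kept for 4 weeks in normoxia or hypoxia. Normoxia was air at normal altitude, with an oxygen pressure of about 150 mmHg, which the labels write as PAO2. Hypoxia was air at the pressure of 18000 feet, with a labelled oxygen pressure of about 70 mmHg. Such hypoxia is a standard way to raise the pressure in the pulmonary circulation of rodents. Each of the 6 groups held 3 libraries, numbered 0 to 2. The labels do not say that each library came from its own animal, so the p-values measure the spread between these libraries. Library totals ran from 16806806 to 25983090 estimated fragments, with the lowest in β-arrestin 1 −/− hypoxia replicate 2 (16806806) and β-arrestin 2 −/− normoxia replicate 0 (18250814). In each library 16839 to 17431 genes had at least 1 fragment.

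The targeted genes were examined first. Arrb1 lies on chromosome 7 from 99535486 to 99606771 (mm10) and Arrb2 on chromosome 11 from 70432580 to 70440828, both protein-coding genes counted over all their exons. Arrb1 fell from 472 ± 7.35 CPM (SD, n = 3) in wild type normoxia to 104 ± 15.3 in β-arrestin 1 −/− normoxia, which is 22.1% of wild type, and from 369 ± 57.9 to 87.7 ± 3.62 in hypoxia, or 23.8%. The log2 changes were -2.18 ± 0.12 (SE, adjusted p = 3.98e-08) and -2.07 ± 0.12 (adjusted p = 8.22e-08). Arrb2 was not lower in the libraries labelled β-arrestin 2 −/−. It stood at 40.7 ± 5.19 CPM against 32.3 ± 2.55 in wild type normoxia (log2 change 0.33 ± 0.20, adjusted p = 0.256), and at 34.4 ± 3.57 against 39.0 ± 5.02 in hypoxia (-0.18 ± 0.20, adjusted p = 0.821). The label of these 6 libraries is therefore not borne out by the level of the gene, and every direction drawn from them below is that of the libraries labelled β-arrestin 2 −/−. A total per gene cannot show which exons were covered. In normoxia these same libraries had less Arrb1 than wild type, 290 ± 28.6 CPM (log2 change -0.70 ± 0.12, adjusted p = 0.00438), a call lost with the tissue score described below as a covariate.

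**Figure D1:**
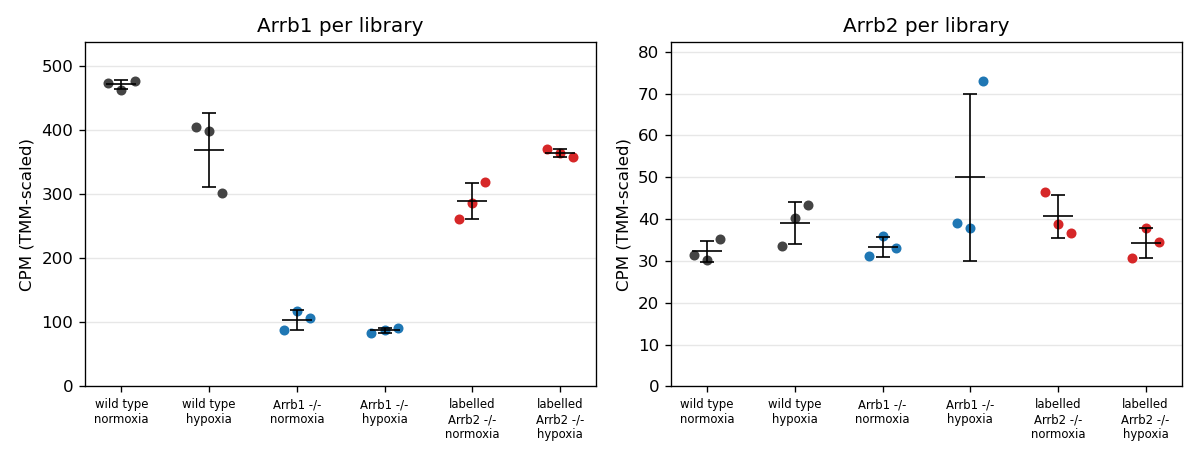
CPM (TMM-scaled, vertical axis from 0) of Arrb1 and Arrb2 in each of the 18 libraries by group; points are libraries, horizontal marks group means and bars SD. Arrb1 averages 104 and 87.7 CPM in the β-arrestin 1 −/− groups, while Arrb2 averages 40.7 and 34.4 CPM in the groups labelled β-arrestin 2 −/−, against 32.3 and 39.0 in wild type.

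What chronic hypoxia changes in the normal lung was asked of the wild type groups. Endothelial genes moved both ways: Plvap, the protein of the diaphragms of endothelial fenestrae, fell by 2.79 ± 0.25 on the log2 scale (from 1183 ± 75.7 to 171 ± 50.6 CPM), and Lyve1, a hyaluronan receptor gene of lymphatic endothelium that is also on the list of monocyte and interstitial macrophage genes, fell by 2.78 ± 0.17. Sox17, a transcription factor of arterial endothelium, rose by 1.09 ± 0.12. Of 32 endothelial genes 4 rose and 4 fell (4 and 7 when adjusted over the list alone), with no one direction (camera adjusted p = 0.0518; adjusted p = 0.599 with an estimated correlation). Ankrd63 (-4.42 ± 0.39) and Doc2b (-4.04 ± 0.56) were among the called genes with large falls. Airway secretory genes were among those with large rises, namely Reg3g (8.42 ± 1.81), Clca3 (7.98 ± 2.00), Bpifb1 (5.99 ± 1.36) and Scgb3a1 (5.40 ± 1.02), together with Gp2, which had 3 fragments in all of wild type normoxia and 780 in hypoxia, a ratio of 233 (95% counting interval 79.9 to 1130). Of 24 club and secretory airway genes 5 rose and 1 fell, 8 and 1 when adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.00279; adjusted p = 0.569 with an estimated correlation), a list call lost without wild type normoxia replicate 2 (adjusted p = 0.0567).

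Pericytes, the mural cells of small vessels, gave the one list whose call held under both correlation settings. Of 17 pericyte genes 5 rose and 0 fell, 11 when adjusted over the list alone (camera adjusted p = 7.63e-07; adjusted p = 0.0397 with an estimated correlation). Lamc3 rose by 1.09 ± 0.19 and Cspg4, the NG2 proteoglycan, by 0.90 ± 0.17. Enzymes of cholesterol and fatty acid synthesis rose in 11 of 30 cases, 17 when adjusted over the list alone, and 0 fell (camera adjusted p = 4.31e-12; adjusted p = 0.294 with an estimated correlation). They included Mvd (1.14 ± 0.18), Dhcr7 (0.87 ± 0.14) and Cyp51 (0.84 ± 0.14). Genes that respond to glucocorticoids and feeding fell in 6 of 22 cases, 10 when adjusted over the list alone, and rose in 1, 2 over the list alone (camera adjusted p = 2.9e-05; adjusted p = 0.294 with an estimated correlation). The fatty acid oxidation gene Cpt1a fell by 0.97 ± 0.12, while Sgk1 rose by 0.82 ± 0.14. Immediate early genes rose in 12 of 31 cases, 21 when adjusted over the list alone, with Egr1 up by 3.67 ± 0.69 (camera adjusted p = 2.02e-08; adjusted p = 0.399 with an estimated correlation). The mean log2 CPM of this list, minus that of all libraries, was 0.4, -0.35 and 1.37 in hypoxia replicates 0 to 2. In wild type normoxia it was -0.53 to -0.49, so the rise differed widely between libraries.

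Lymphocyte and macrophage genes were also higher on average in wild type hypoxia. Scores per library (mean log2 CPM of members minus the mean over all libraries) overlapped for B and plasma cells, -0.14 to 1.39 against -1.35 to -0.11 in normoxia. They also overlapped for alveolar macrophages, 0.03 to 0.3 against -1.03 to 0.14. T and NK cell scores were -0.14 to 0.64 against -1.24 to -0.2, with no overlap. The lowest scores were those of wild type normoxia replicate 1. T and NK cell genes rose in 9 of 36 cases, 24 when adjusted over the list alone (Cd8b1 up by 2.23 ± 0.40; camera adjusted p = 5.62e-15; adjusted p = 0.294 with an estimated correlation). B and plasma cell genes rose in 9 of 26 cases, 21 when adjusted over the list alone (Faim3 up by 2.62 ± 0.57; camera adjusted p = 1.92e-12; adjusted p = 0.294 with an estimated correlation). Alveolar macrophage genes rose in 5 of 23, 12 when adjusted over the list alone (the protease Ctsk up by 1.36 ± 0.14; camera adjusted p = 9.69e-08; adjusted p = 0.294 with an estimated correlation). Neutrophil genes had a median of 1.17 with 1 of 23 called, 2 when adjusted over the list alone (camera adjusted p = 1.93e-06; adjusted p = 0.399 with an estimated correlation). Of 39 inflammatory cytokine and adhesion genes 7 rose and 1 fell, 12 and 4 when adjusted over the list alone (camera adjusted p = 0.00118; adjusted p = 0.308 with an estimated correlation). Ptx3 rose by 2.75 ± 0.38 and the adhesion receptor gene Vcam1 fell by 0.94 ± 0.13. The prostacyclin receptor gene Ptgir rose by 1.24 ± 0.17 and Bmp3 by 0.69 ± 0.09. Of 35 targets of hypoxia-inducible factors and glycolysis genes 3 rose, Aldoc by 1.04 ± 0.17, and 1 fell, 5 and 3 when adjusted over the list alone (camera adjusted p = 0.16). Cardiac muscle genes had a median log2 change of 2.45 over 28 members with 0 called (camera adjusted p = 3.89e-12; adjusted p = 0.399 with an estimated correlation). A combined score of the cardiac muscle, club and secretory airway and adipocyte lists was -1.20, -2.15 and -0.97 in the wild type normoxia libraries and 0.26 to 0.66 in wild type hypoxia, so it moved with all of these groups.

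In all, 738 of 15387 tested genes changed with hypoxia in wild type lung, 442 higher and 296 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Of these, 562 (76.2%) were also called, in the same direction, in the authors' deposited table, which called 1291 of the genes tested here. With the combined score as a covariate, an alternative chosen after seeing the data, 67 genes were called, and 19 of the 35 genes named for this comparison lost their calls (adjusted p of 0.0653 to 0.62), namely Clca3, Gp2, Bpifb1, Scgb3a1, Doc2b, Lamc3, Cspg4, Egr1, Dhcr7, Cyp51, Sgk1, Cd8b1, Faim3, Aldoc, Stc1, Hilpda, Hey2, Pgf and Cd34. Bpifb1 and Scgb3a1 are part of the score, so their losses follow partly from it and count for little. The folds stayed of similar size (median ratio 0.88) while the median SE went from 0.18 to 0.23. The count was 209 without wild type normoxia replicate 1 (highest 943 without wild type hypoxia replicate 0). Bpifb1, Clca3, Cspg4, Egr1, Faim3, Pgf, Reg3g and Stc1 lost their calls without at least 1 of 5 libraries, at adjusted p of 0.0509 to 0.133.

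The hypoxia response was next measured within β-arrestin 1 −/− lung. Lyve1 fell by 2.95 ± 0.18, Ankrd63 by 3.03 ± 0.37 and Plvap by 2.38 ± 0.25. Slc26a10, an anion transporter family member, rose by 3.49 ± 0.25, Ntrk2, the receptor of brain-derived neurotrophic factor, by 3.50 ± 0.55 and Sox17 by 1.08 ± 0.12. The lipoxygenase gene Alox15 (4.10 ± 0.97), the lubricin gene Prg4 (3.65 ± 0.83) and the neutrophil alarmin gene S100a8 (3.21 ± 0.78) also rose, and Serpina3f (-2.94 ± 0.54), Zbtb16 (-2.59 ± 0.65) and Pdk4 (-2.42 ± 0.51) fell. Neutrophil genes rose in 5 of 23 cases, 15 when adjusted over the list alone, with Ngp of the granules up by 3.28 ± 0.66 (camera adjusted p = 2.77e-09; adjusted p = 0.371 with an estimated correlation). Sterol and fatty acid synthesis genes rose in 9 of 30 cases, 17 when adjusted over the list alone, with Mvd up by 1.13 ± 0.18 (camera adjusted p = 4.18e-09; adjusted p = 0.371 with an estimated correlation). Glucocorticoid and feeding-responsive genes fell in 6 of 22, 13 when adjusted over the list alone, and rose in 1, 2 over the list alone (camera adjusted p = 7.7e-07; adjusted p = 0.371 with an estimated correlation). Cpt1a fell by 0.73 ± 0.12, while Sgk1 rose by 1.34 ± 0.14. Among 21 arrestin and receptor kinase genes Rgs2 (1.12 ± 0.15) and Adrb3 (1.15 ± 0.17) rose and Txnip fell by 0.66 ± 0.11, 4 and 4 when adjusted over the list alone (camera adjusted p = 0.936). Tfrc, the transferrin receptor, rose by 0.93 ± 0.15, Bmp3 by 0.64 ± 0.09 and Ptx3 by 2.31 ± 0.40. The cystine transporter gene Slc7a11 fell by 1.68 ± 0.23 and Vcam1 by 1.10 ± 0.13.

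In total 456 genes changed, 285 higher and 171 lower, and 352 (77.2%) were also called in the authors' deposited table. That table called 1113 of the genes tested here. The count was 133 without β-arrestin 1 −/− normoxia replicate 0 (highest 513 without β-arrestin 1 −/− hypoxia replicate 0) and 47 when only these 6 libraries were fitted. Without β-arrestin 1 −/− hypoxia replicate 0 the log2 change of Alox15 was 2.05 and that of Prg4 1.82, so this library carried much of both. With the combined score as a covariate Alox15 and S100a8 were not called (adjusted p of 0.0549 to 0.0727). Alox15, Hilpda, Ngp, Pdk4, Pgf, Prg4, S100a8, Stc1 and Zbtb16 lost their calls without at least 1 of the 6 libraries, at adjusted p of 0.054 to 0.172.

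In the libraries labelled β-arrestin 2 −/−, hypoxia changed more genes. Matrix genes fell: of 37 collagen and matrix genes 17 fell and 4 rose (19 and 5 when adjusted over the list alone; camera adjusted p = 0.00487; adjusted p = 0.735 with an estimated correlation). The crosslinking enzyme gene Loxl1 fell by 1.43 ± 0.16, Timp1 by 2.13 ± 0.26, Tnc by 1.89 ± 0.24 and Col3a1 by 1.85 ± 0.25. Smooth muscle contractile genes fell in 6 of 23 cases, also 6 when adjusted over the list alone, including Acta2 (-1.19 ± 0.24) and Cnn1 (-1.48 ± 0.31; camera adjusted p = 0.0399; adjusted p = 0.735 with an estimated correlation). Circadian clock genes rose in 12 of 22 cases and fell in 1 (14 and 1 when adjusted over the list alone; camera adjusted p = 0.000414; adjusted p = 0.3 with an estimated correlation). The clock output genes Tef, Hlf and Dbp rose by 1.72 ± 0.21, 2.06 ± 0.34 and 3.33 ± 1.04. Pericyte genes rose in 7 of 17, 9 when adjusted over the list alone, led by Lamc3 (2.24 ± 0.20) and Notch3 (0.88 ± 0.20; camera adjusted p = 0.00109; adjusted p = 0.281 with an estimated correlation). Mesothelial genes fell in 8 of 16, 11 when adjusted over the list alone, such as Wt1 (-2.09 ± 0.34) and Upk3b (-1.75 ± 0.37; camera adjusted p = 0.000617; adjusted p = 0.735 with an estimated correlation). Dendritic cell and MHC class II genes fell in 13 of 25 and rose in 2 (13 and 3 when adjusted over the list alone; camera adjusted p = 0.00211; adjusted p = 0.735 with an estimated correlation). Ccl22 fell by 2.30 ± 0.28 and Mgl2 by 1.18 ± 0.16. Interferon-stimulated genes fell in 13 of 40 and rose in 1 (15 and 3 when adjusted over the list alone), Mx1 by 1.80 ± 0.36 (camera adjusted p = 0.0229; adjusted p = 0.735 with an estimated correlation).

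Vessel tone genes moved both ways in these libraries, 15 of 45 higher and 8 lower (17 and 9 when adjusted over the list alone; camera adjusted p = 0.0425; adjusted p = 0.735 with an estimated correlation). Edn1, the gene of the vasoconstrictor endothelin 1, rose by 1.91 ± 0.27, Ace by 1.19 ± 0.20, the angiotensin receptor gene Agtr1a by 0.97 ± 0.12 and Ramp3 by 1.62 ± 0.20. Within the BMP and TGF-beta pathway 11 of 37 genes rose and 4 fell (12 and 4 when adjusted over the list alone; camera adjusted p = 0.0339; adjusted p = 0.735 with an estimated correlation). Smad9 rose by 1.20 ± 0.20 and Bmp4 by 0.83 ± 0.14. Of the hypoxia-inducible factor targets and glycolysis genes 8 of 35 rose and 2 fell (11 and 3 when adjusted over the list alone; camera adjusted p = 0.0399; adjusted p = 0.735 with an estimated correlation). Mxi1 rose by 0.90 ± 0.10 and Car9 fell by 1.44 ± 0.29. Other genes that rose were Ntrk2 (4.04 ± 0.57), Slc26a10 (3.23 ± 0.25), Cntn1 (2.80 ± 0.44) and Snph (2.67 ± 0.30). Spon2 (-4.77 ± 0.40), Olfm2 (-3.34 ± 0.33), Plvap (-2.91 ± 0.25) and Nr4a3 (-2.53 ± 0.75) fell, as did Rps18 (-7.04 ± 1.28), a ribosomal protein gene with near-identical copies among which fragments can be moved, so its level is uncertain.

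Here 3374 genes changed, 1708 higher and 1666 lower, of which 1954 (57.9%) were also called in the authors' deposited table. That table called 2624 of the genes tested here. The count ranged from 1708 without β-arrestin 2 −/− hypoxia replicate 0 to 3106 without β-arrestin 2 −/− normoxia replicate 2. Camera's calls were lost in 3 of 6 leave-one-out fits for smooth muscle (without normoxia replicate 0 and hypoxia replicates 1 and 2, adjusted p up to 0.581) and, without the same libraries, for vessel tone genes (up to 0.136). They were lost in 2 of 6 for hypoxia-inducible factor targets (without normoxia replicates 1 and 2, up to 0.0826), without normoxia replicate 0 for the BMP and TGF-beta pathway (0.0673) and without hypoxia replicate 2 for interferon-stimulated genes (0.105). Without normoxia replicate 0 Acta2 was at -0.73 and Cnn1 at -0.88, and without hypoxia replicate 0 Dbp was at 1.37 (adjusted p = 0.321). With the combined score as a covariate Dbp and Cd34 were not called (adjusted p of 0.0517 to 0.0586). Cd34, Dbp, Hilpda and Nr4a3 lost their calls without at least 1 library, at adjusted p of 0.0524 to 0.321.

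**Figure D2:**
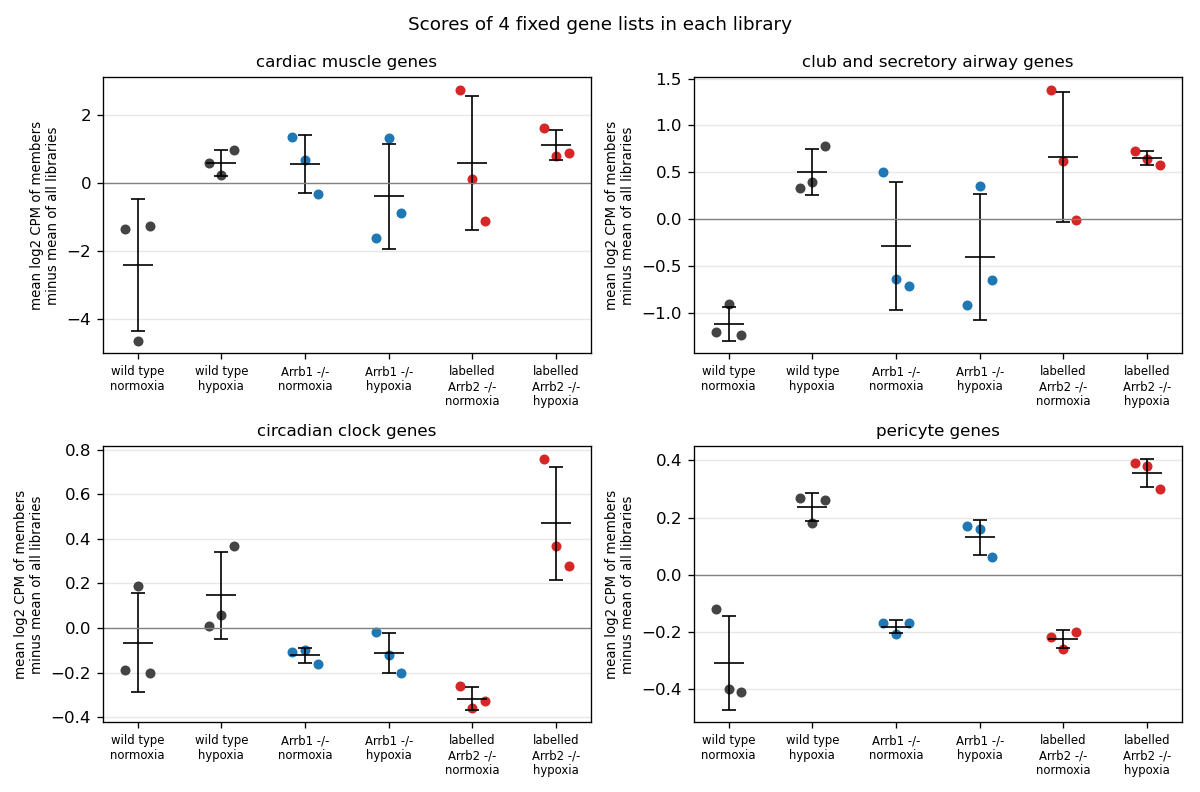
Score of 4 gene lists in each library (vertical axes: mean log2 CPM of the members minus the mean over all 18 libraries); points are libraries, horizontal marks group means and bars SD. Pericyte scores lie above 0 in all 9 hypoxia libraries and below 0 in all 9 normoxia libraries, clock scores reach 0.28 to 0.76 in the hypoxia libraries labelled β-arrestin 2 −/−, and cardiac muscle scores range from -4.66 in wild type normoxia replicate 1 to 2.74 in normoxia replicate 0 of that line.

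Genes changed by hypoxia in each genotype were then set side by side. In all 3 genotypes 82 genes rose and 35 fell, where independent lists would share 0.91 and 0.36. Ntrk2 rose by 4.59, 3.50 and 4.04 on the log2 scale in wild type, β-arrestin 1 −/− and the libraries labelled β-arrestin 2 −/−, and Slc26a10 by 4.48, 3.49 and 3.23. Plvap fell by 2.79, 2.38 and 2.91 and Olfm2 by 2.69, 2.04 and 3.34. Lyve1, Ankrd63 and Vcam1 fell in each, and Sox17, Ptx3 and Sgk1 rose in each. Wild type and β-arrestin 1 −/− lung shared 148 genes that rose and 74 that fell, where 8.2 and 3.3 were expected of independent lists, and 0 went opposite ways (Pearson r = 0.34 across genes, which are not independent replicates). Wild type and the libraries labelled β-arrestin 2 −/− shared 138 and 88, where 49.1 and 32 were expected, with 41 opposite (r = 0.18). β-Arrestin 1 −/− and the latter shared 130 and 67, where 31.6 and 18.5 were expected, with 15 opposite (r = 0.18).

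**Figure D3:**
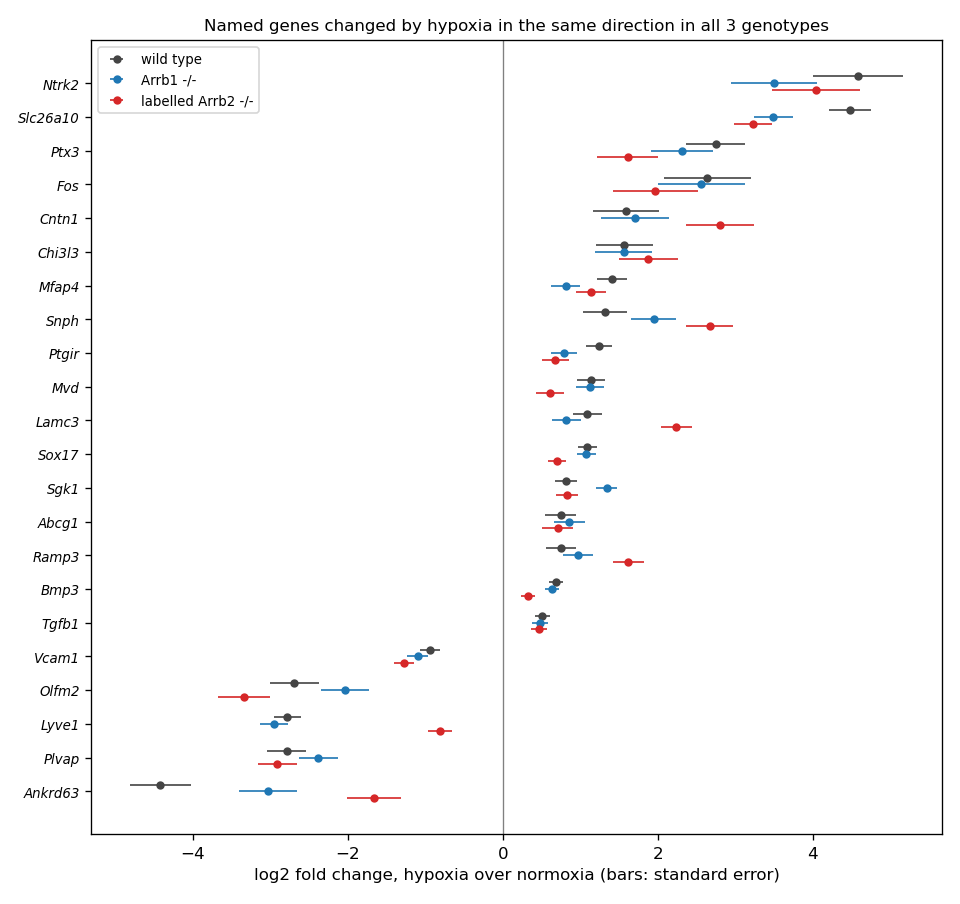
Log2 fold change (hypoxia over normoxia, horizontal axis; bars are SE) in each of the 3 genotypes for named genes that changed in the same direction in all 3. Ntrk2 lies at 4.59, 3.50 and 4.04, Plvap at -2.79, -2.38 and -2.91, in wild type, β-arrestin 1 −/− and the libraries labelled β-arrestin 2 −/−.

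Whether loss of an arrestin alters the response to hypoxia was tested as an interaction. For β-arrestin 1 −/− against wild type, edgeR's quasi-likelihood test called 0 genes, with 897 at an unadjusted p under 0.05, and DESeq2 called 9. Among the genes with the smallest p were Sele (-3.08 ± 0.56, adjusted p = 0.351), Hpgd (1.35 ± 0.26, adjusted p = 0.401), Fer1l4 (-2.82 ± 0.55, adjusted p = 0.418) and Slc45a4 (0.74 ± 0.15, adjusted p = 0.418), none of which passed. Cardiac muscle genes had a median interaction of -2.91 (camera adjusted p = 6.29e-21; adjusted p = 0.536 with an estimated correlation), smooth muscle genes of -0.48 (camera adjusted p = 2.08e-06; adjusted p = 0.536 with an estimated correlation) and dendritic cell and MHC class II genes of -0.40 (camera adjusted p = 0.000302; adjusted p = 0.536 with an estimated correlation). Inflammatory genes were lower (median -0.38, camera adjusted p = 0.00124; adjusted p = 0.536 with an estimated correlation; 0.0746 without wild type hypoxia replicate 2). Endothelial genes were higher (median 0.23, camera adjusted p = 0.00321; adjusted p = 0.559 with an estimated correlation; up to 0.161 without wild type normoxia replicate 0 or hypoxia replicate 2). No member of these lists was called over all genes. Adjusted over the list alone, 1 dendritic cell gene was higher and 2 inflammatory genes lower. These lists moved the same way in the interaction of the other line, cardiac muscle genes among them (camera adjusted p = 0.000263; adjusted p = 0.758 with an estimated correlation). Collagen and matrix genes, given next for that line, were also lower here (camera adjusted p = 0.0271; adjusted p = 0.806 with an estimated correlation), a call lost in 6 of 12 leave-one-out fits. Both interactions subtract the response of the same wild type libraries, which alone can make them move alike. The shifts are therefore not shown to be particular to either line.

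For the libraries labelled β-arrestin 2 −/−, the hypoxia response differed from that of wild type in 932 genes, 537 with a more positive and 395 with a more negative response. Collagen and matrix genes were more negative in 9 of 37 cases, 18 when adjusted over the list alone (camera adjusted p = 1.39e-06; adjusted p = 0.505 with an estimated correlation). Loxl1 was at -1.60 ± 0.22, Tnc at -1.91 ± 0.33 and the elastin gene Eln at -1.92 ± 0.34. In wild type hypoxia 5 of the 37 had risen and 0 fallen, 8 and 2 when adjusted over the list alone, and the interaction subtracts that response. Camera's adjusted p there was 0.00307, or 0.599 with an estimated correlation, and 0.0926 without wild type normoxia replicate 1. Dendritic cell and MHC class II genes were more negative in 9 of 25 and more positive in 1 (15 and 1 when adjusted over the list alone), such as Ccl22 (-2.23 ± 0.38) and Fscn1 (-1.64 ± 0.29; camera adjusted p = 1.94e-06; adjusted p = 0.505 with an estimated correlation). Inflammatory cytokine and adhesion genes were more negative in 8 of 39, 14 when adjusted over the list alone, with Nfkb2 at -0.87 ± 0.14 (camera adjusted p = 6.54e-05; adjusted p = 0.505 with an estimated correlation). Smooth muscle genes were more negative in 6 of 23, 12 when adjusted over the list alone, with Acta2 at -1.61 ± 0.34 (camera adjusted p = 2.94e-05; adjusted p = 0.525 with an estimated correlation). In wild type hypoxia 1 of the 23 had risen and 0 fallen, 3 and 0 when adjusted over the list alone. Camera's adjusted p there was 0.000207, or 0.551 with an estimated correlation. Sterol synthesis genes were more negative in 7 of 30, also 7 when adjusted over the list alone, with Cyp51 at -1.15 ± 0.20 (camera adjusted p = 0.00639; adjusted p = 0.734 with an estimated correlation), a list call lost without replicates 1 and 2, each in turn, of normoxia in the line labelled β-arrestin 2 −/− (adjusted p up to 0.0606). Endothelial genes were more positive in 8 of 32 and more negative in 1 (14 and 4 when adjusted over the list alone), with Lyve1 at 1.97 ± 0.23 (camera adjusted p = 0.000277; adjusted p = 0.505 with an estimated correlation). Glucocorticoid and feeding-responsive genes were more positive in 5 of 22, 6 when adjusted over the list alone (camera adjusted p = 0.000742; adjusted p = 0.505 with an estimated correlation). Cpt1a was at 1.17 ± 0.17 and Ucp2 at 1.06 ± 0.16. Clock genes were more positive in 2 of 22, 8 when adjusted over the list alone, with a median of 0.71 (camera adjusted p = 0.00333; adjusted p = 0.505 with an estimated correlation). Tef of the clock list (1.81 ± 0.30), Epas1, the gene of HIF-2α (1.08 ± 0.19), Edn1 (1.95 ± 0.37) and Arrb1 (0.69 ± 0.17) were more positive.

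Among the most positive interactions were those of Doc2b (4.98 ± 0.73), Zbtb16 (4.24 ± 0.91), Myrip (3.63 ± 0.59) and Hif3a (2.96 ± 0.63). Doc2b lies within 10 Mb of Arrb2, in the window counted below. Among the most negative were those of Clca3 (-13.37 ± 2.63), Reg3g (-8.56 ± 2.15), Rps18 (-7.06 ± 1.53), Bpifb1 (-6.69 ± 1.69) and Gp2 (-6.05 ± 1.61). With the combined score of cardiac muscle, airway and fat lists as a covariate the 932 became 126, and 8 of the 24 named genes lost their calls (adjusted p of 0.0655 to 0.156), namely Zbtb16, Hif3a, Clca3, Rps18, Bpifb1, Gp2, Acta2 and Arrb1, of which Bpifb1 is itself part of the score. The count was 322 without wild type normoxia replicate 1 and 2017 without wild type hypoxia replicate 0. Arrb1, Bpifb1, Gp2, Reg3g, Rps18 and Zbtb16 lost their calls without at least 1 of 10 libraries, at adjusted p of 0.0503 to 0.094. Without β-arrestin 2 −/− normoxia replicate 0 the interaction of Reg3g was at -6.6. The normoxia difference of Clca3 from wild type was then at 3.78, so this library carried part of both.

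In the main fit few genes set β-arrestin 1 −/− lung apart from wild type within an exposure, while DESeq2 and the authors' table called more, as given below. In normoxia 35 genes differed, 13 higher and 22 lower, and in hypoxia 31, 13 higher and 18 lower. Neighbours of Arrb1 on chromosome 7 were among the genes that differed. The tripartite motif gene Trim12a had 1 fragment in β-arrestin 1 −/− normoxia and 1072 in wild type, a ratio of 1120 (95% counting interval 201 to 44300). It had 0 fragments in hypoxia, at least 295-fold lower by a floor of 3 fragments over the group. Trim30d fell by 7.05 ± 0.30 in normoxia and was at least 225-fold lower in hypoxia, Trim34a fell by 2.82 ± 0.21 and 3.02 ± 0.22, and the unconventional myosin gene Myo7a by 1.76 ± 0.12 and 1.88 ± 0.12. Trim34b rose by 5.30 ± 0.63 and 4.07 ± 0.56. The Trim genes belong to a family between whose members fragments can be exchanged, but the sum of 7 members was 58.8% of wild type in normoxia and 71.6% in hypoxia. The protocadherin Pcdhgb8 rose by 2.81 ± 0.29 and 2.94 ± 0.29, the deacetylase gene Hdac1 by 1.84 ± 0.22 and 2.19 ± 0.23 and the nucleosome-binding gene Hmgn2 by 1.96 ± 0.19 and 1.89 ± 0.18. The last 2 lie on chromosome 4 and did not set this line apart: in the libraries labelled β-arrestin 2 −/− Hmgn2 rose by 2.23 ± 0.19 and 2.01 ± 0.18 and, in normoxia, Hdac1 by 1.43 ± 0.22, and the 10 Mb from 130 Mb on that chromosome held 3 genes called alike in both exposures in each line. In normoxia Sfn (1.97 ± 0.35) and the cardiac myosin gene Myh7 (1.43 ± 0.27) rose, and in hypoxia the heat shock gene Hspb1 (1.44 ± 0.26) and the capillary carbonic anhydrase gene Car4 (0.86 ± 0.11) rose and Alpl fell by 3.49 ± 0.45. Cardiac muscle genes were higher in normoxia by a median of 2.52 on the log2 scale, with 1 of 28 called, 26 when adjusted over the list alone (camera adjusted p = 2.18e-21; adjusted p = 0.484 with an estimated correlation), beside a combined tissue score of -0.51 to 0.76 against -2.15 to -0.97 in wild type. Heat shock genes were higher in both exposures (medians 0.60 and 0.48 over 21 members, 0 and 1 called, 11 and 3 when adjusted over the list alone). Camera adjusted p were 6.04e-11 and 9.89e-05 (adjusted p = 0.561 and adjusted p = 0.842 with an estimated correlation). So were ER stress genes (medians 0.27 and 0.16 over 26 members, 0 and 1 called, 7 and 5 when adjusted over the list alone), with camera adjusted p of 3.96e-10 and 0.00015 (adjusted p = 0.408 and adjusted p = 0.842 with an estimated correlation). Both hypoxia calls were lost without β-arrestin 1 −/− hypoxia replicate 0 (adjusted p = 0.164 and 0.197).

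The authors' deposited table also called 31 of the 35 and 27 of the 31 genes, the latter with 25 in the same direction. It called far more of the genes tested here, 616 in normoxia and 645 in hypoxia, so the number of genes depended on the test. With the combined score as a covariate 14 and 24 were called, and Sfn, Myh7 (adjusted p of 0.46 to 0.467) and Hspb1 (0.0939) were not, Myh7 being part of the score. Leaving out 1 library gave 15 (without β-arrestin 1 −/− normoxia replicate 0) to 30 genes in normoxia and 20 (without wild type hypoxia replicate 1) to 36 in hypoxia, with DESeq2 at 176 and 154. In hypoxia DESeq2 called 97 higher and 57 lower, and limma on log2(FPKM + 1) 15 and 15, against 13 and 18 in the main fit. The balance of directions there thus depended on the test. Sfn and Myh7 (adjusted p of 0.0775 to 0.282) and Hspb1 (0.103 to 0.184) lost their calls without at least 1 library.

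The libraries labelled β-arrestin 2 −/− differed from wild type in 1461 genes in normoxia, 615 higher and 846 lower. A pseudogene of an MHC class II alpha chain, H2-Ea-ps, rose by 10.61 ± 0.47 on the log2 scale, and airway secretory genes rose as well: Bpifa1 (8.75 ± 2.12), Reg3g (7.48 ± 1.79) and Clca3 (6.99 ± 2.03). Of 24 club and secretory airway genes 8 rose, with 12 higher and 1 lower when adjusted over the list alone (camera adjusted p = 5.05e-05; adjusted p = 0.653 with an estimated correlation). Tff2 rose by 5.04 ± 1.00 and Scgb3a1 by 4.85 ± 0.99. Cardiac muscle genes rose in 12 of 28 cases, 26 when adjusted over the list alone, with the natriuretic peptide gene Nppa up by 7.55 ± 2.10 (camera adjusted p = 1.46e-08; adjusted p = 0.653 with an estimated correlation). Smooth muscle genes rose in 12 of 23, 18 when adjusted over the list alone, with Cnn1 up by 1.54 ± 0.31 (camera adjusted p = 1.86e-06; adjusted p = 0.653 with an estimated correlation). Sterol synthesis genes rose in 7 of 30, 10 when adjusted over the list alone (camera adjusted p = 0.000892; adjusted p = 0.653 with an estimated correlation). Cyp51 rose by 1.15 ± 0.14, Sc4mol by 0.77 ± 0.13 and Dhcr7 by 0.78 ± 0.14. The mast cell protease gene Tpsb2 rose by 4.25 ± 0.66 and the lectin gene Clec10a, which lies within 10 Mb of Arrb2, by 1.71 ± 0.32. Zbtb16 (-3.40 ± 0.68), the proton pump subunit gene Atp6v0c (-2.77 ± 0.14), Cd300lg (-2.76 ± 0.23), Myrip (-2.73 ± 0.43) and Tcf23 (-1.98 ± 0.44) fell. Atp6v0c lies on chromosome 17 from 24163865 to 24169429, near other genes called alike in both exposures in this line. Endothelial genes fell in 9 of 32 and rose in 1 (13 and 1 when adjusted over the list alone), Lyve1 by 1.15 ± 0.16 (camera adjusted p = 0.000394; adjusted p = 0.653 with an estimated correlation). Cpt1a fell by 1.04 ± 0.12 and Tef by 1.17 ± 0.21. The combined tissue score was 1.78, 0.20 and -0.52 in these 3 libraries against -0.97 to -2.15 in wild type normoxia, so it moved with these groups.

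The authors' deposited table called 989 of the 1461 genes, and 2096 of all genes tested here. With the combined score as a covariate 31 genes were called, and 17 of the 26 named genes lost their calls (adjusted p of 0.0735 to 0.968), namely Bpifa1, Nppa, Reg3g, Clca3, Zbtb16, Myrip, Tcf23, Cnn1, Dhcr7, Lyve1, Tff2, Scgb3a1, Tpsb2, Clec10a, Tef, Arrb1 and Hdac1. Bpifa1, Nppa, Reg3g, Tff2 and Scgb3a1 are part of the score, so their losses follow partly from it. The median ratio of log2 changes was 0.78 and the median SE went from 0.15 to 0.20. Leaving out 1 library gave 314 (without β-arrestin 2 −/− normoxia replicate 0) to 1918 (without replicate 2 of that group). Without β-arrestin 2 −/− normoxia replicate 0 Clca3 was at 3.78 (adjusted p = 0.33) and Cnn1 at 0.94. Bpifa1, Clca3, Nppa, Reg3g and Tcf23 lost their calls without at least 1 of 5 libraries, at adjusted p of 0.0569 to 0.33.

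In hypoxia 142 genes differed, 53 higher and 89 lower. H2-Ea-ps had 0 fragments in wild type hypoxia and 16829 in these libraries, at least 5710-fold higher. Other genes of the major histocompatibility region of chromosome 17 rose as well, namely H2-Q10 (5.29 ± 0.61), H2-M2 (4.46 ± 0.45), H2-Q2 (4.22 ± 0.33) and the complement gene C4a (4.33 ± 0.37), while H2-Ob fell by 2.83 ± 0.35. Several are close paralogs whose fragments can be exchanged. Atp6v0c (-2.64 ± 0.13), which also lies on chromosome 17, Dnase1l3 (-2.47 ± 0.38), Spon2 (-2.39 ± 0.38) and Rps18 (-7.94 ± 1.25) also fell. Of 37 collagen and matrix genes 6 fell, 17 when adjusted over the list alone, with Loxl1 down by 1.34 ± 0.16 and Eln by 1.54 ± 0.25 (camera adjusted p = 3.5e-12; adjusted p = 0.3 with an estimated correlation). Dendritic cell and MHC class II genes fell in 3 of 25, with 13 lower and 1 higher when adjusted over the list alone, Ccl22 by 1.70 ± 0.28 (camera adjusted p = 3.48e-08; adjusted p = 0.3 with an estimated correlation). This list holds class II genes of the major histocompatibility region and Clec10a near Arrb2. Their levels may differ in this line for reasons of position, and the list was not tested without them. The authors' deposited table called 128 of the 142, and 757 of all genes tested here. Leaving out 1 library gave 52 (without β-arrestin 2 −/− hypoxia replicate 2) to 302 genes (without wild type hypoxia replicate 0), and limma on log2(FPKM + 1) moved the share of higher calls from 37.3% to 50.5%.

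β-Arrestin 1 −/− and the libraries labelled β-arrestin 2 −/− were compared with the same wild type libraries, which alone makes their differences correlate. In normoxia 6 genes were higher and 9 lower in both lines, where 0.5 and 1.2 were expected of independent lists. The fold changes correlated at r = 0.66 across genes against 0.5 in 20 simulations (covariance 0.188 against 0.0473). In hypoxia 4 and 2 genes were shared, where 0 and 0.1 were expected, with r = 0.26 against a simulated 0.49 and a covariance of 0.0472 against 0.0427. The expectation for independent lists ignores the shared controls. Simulated unchanged groups against the same controls shared 0 calls, but such groups give almost no calls, so the shared counts have no comparison value here, and 3 wild type libraries cannot be split into 2 sets of 2.

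Calls were then counted within 10 Mb of the targeted gene, which was left out. In β-arrestin 1 −/− lung 5 of 150 genes in the Arrb1 window were called in normoxia against 29 of 15230 elsewhere (odds ratio 18, Fisher's exact test, two-sided, p = 1.83e-05), and 5 of 150 against 25 in hypoxia (odds ratio 20.9, Fisher's exact p = 9.66e-06). They were Myo7a, Trim34a, Trim12a, Trim34b and Trim30d in both. Fisher's exact test takes genes as independent, but the Trim genes are neighbouring members of a family that can exchange fragments. The same 5 genes also count in both exposures, so these p-values overstate the evidence. In the libraries labelled β-arrestin 2 −/−, 54 of 325 genes of the Arrb2 window (16.62%) were called in normoxia against 9.34% elsewhere (odds ratio 1.93, Fisher's exact p = 4.82e-05). In hypoxia 10 of 325 were called against 132 of 15055 (odds ratio 3.59, Fisher's exact p = 0.000876). Called alike in both were 4 of the 325, among them the apoptosis-associated gene Xaf1 (2.60 ± 0.22 and 2.29 ± 0.22) and Tlcd2 (1.55 ± 0.23 and 1.88 ± 0.24). Another gene called in both went opposite ways, and the other normoxia calls of this window were not called in hypoxia. The normoxia contrast fell from 1461 to 31 calls with the tissue score, and the window was not counted again with it. Genes of this window are not independent either. Over these 4 tests the adjusted p were 3.66e-05, 3.66e-05, 6.43e-05 and 0.000876. The window of the other arrestin held no such excess in any of the 4 contrasts (Fisher's exact p of 0.402 to 1).

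**Figure D4:**
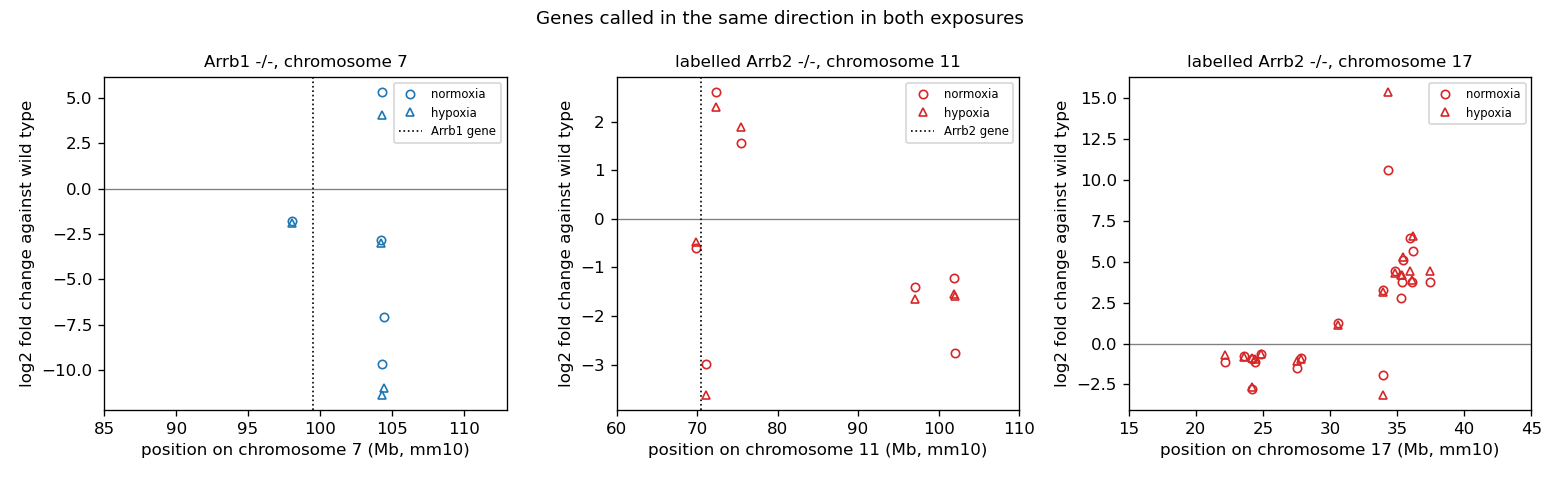
Log2 fold change against wild type (vertical axis) by position (horizontal axis, Mb, mm10) of genes called in the same direction in both exposures, in normoxia (circles) and hypoxia (triangles), on chromosomes 7, 11 and 17; dotted lines mark the targeted gene. On chromosome 7 Myo7a and 4 Trim genes lie on either side of Arrb1, and on chromosome 17 H2-Ea-ps reaches 10.61 and 15.37, a fitted value that depends on the prior count.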

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

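The readings of all tests named in this part were fixed after their results were seen; the windows around the targeted genes and the counts of other splits were planned. The hypoxia response of the libraries labelled β-arrestin 2 −/− differed from that of wild type in 932 genes by the interaction test, which is what singled it out. Arrb2 was not lower in these libraries, so the direction is that of the label. Interaction log2 changes of the named genes were 4.98 for Doc2b, 4.24 for Zbtb16, 3.63 for Myrip, 2.96 for Hif3a, 1.97 for Lyve1, 1.95 for Edn1, 1.81 for Tef, 1.17 for Cpt1a, 1.08 for Epas1, 1.06 for Ucp2 and 0.69 for Arrb1. They were -13.37 for Clca3, -8.56 for Reg3g, -7.06 for Rps18, -6.69 for Bpifb1, -6.05 for Gp2, -2.23 for Ccl22, -1.92 for Eln, -1.91 for Tnc, -1.64 for Fscn1, -1.61 for Acta2, -1.60 for Loxl1, -1.15 for Cyp51 and -0.87 for Nfkb2. Of these, Doc2b lies within 10 Mb of Arrb2.

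The explanations of this interaction were weighed. One library as the whole cause was argued against, since 322 genes were still called in the fit that lost most, the one without wild type normoxia replicate 1. Heart, airway and fat content that differs between libraries stays open: with its score in the fit 126 genes were called, 123 of them among the 932, while the median ratio of their log2 changes was 0.88 and the median SE went from 0.22 to 0.23, and the score was low in all wild type normoxia libraries, so group and content cannot be told apart. Another time of day or day of sampling also stays open: the clock list had a median interaction of 0.71, and no time is given. A biological difference of the line is untested beyond this.

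In the fit of these 12 libraries alone, 2 of 60 splits drawn, the real one included, called as many as the 1546 genes of the real split. The other split called 2638 genes, kept both normoxia groups whole and exchanged 1 hypoxia library each way. Why it called more was not tested. Another split with whole normoxia groups called 356 genes, and splits that mixed the normoxia groups called at most 1. Splits with whole normoxia groups keep the normoxia difference between this line and wild type. In the fit of all 18 libraries that difference held 1461 genes, against 142 in hypoxia. Since a split with mixed hypoxia groups called more genes than the real one, these splits cannot exclude chance for the part the hypoxia groups play. For the interaction of β-arrestin 1 −/−, 5 of 60 splits gave as many as the 1 gene called in that fit (highest other 1), so chance cannot be excluded. Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. In each, 1 of 10, the real one, gave as many. The real and highest other counts were 495 and 2 for hypoxia in wild type, 47 and 0 in β-arrestin 1 −/−, 4264 and 0 in the libraries labelled β-arrestin 2 −/−, 107 and 0 for β-arrestin 1 −/− in normoxia, 12 and 0 in hypoxia, and 2642 and 0, then 84 and 1, for the other line.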

How the results depend on the processing

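In the simulated data, at 1 depth and 3 libraries per group, 43.3% of 1.5-fold changes were called. DESeq2 called 1280 genes for hypoxia in wild type, 841 in β-arrestin 1 −/−, 176 and 154 for β-arrestin 1 −/− in normoxia and hypoxia, 2754 and 481 for the libraries labelled β-arrestin 2 −/−, and 9 and 1875 for the interactions of the lines in that order. Fitting only the groups compared called 47 for hypoxia in β-arrestin 1 −/−, 107 and 12 for β-arrestin 1 −/− in normoxia and hypoxia, 2642 and 84 for the libraries labelled β-arrestin 2 −/−, and 1 and 1546 for the interactions. Limma on log2(FPKM + 1) with no filter called 2 genes for the interaction of β-arrestin 1 −/−. Of 2 alternatives chosen after seeing the data, leaving out the 2 lowest libraries called 1456 for hypoxia in wild type, 87 for β-arrestin 1 −/− in normoxia, 352 for the other line in hypoxia and 1498 for its interaction. The tissue score as a covariate called 67 for hypoxia in wild type, 14 and 31 for the lines in normoxia and 126 for the interaction of the libraries labelled β-arrestin 2 −/−. The cause of these shifts was not tested.

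Leave-one-out counts ran from 209 to 943 for hypoxia in wild type, 133 to 513 in β-arrestin 1 −/− and 1708 to 3106 in the libraries labelled β-arrestin 2 −/−; for the lines against wild type from 15 to 30 and 314 to 1918 in normoxia and 20 to 36 and 52 to 302 in hypoxia; and for the interactions 0 to 0 and 322 to 2017. All other planned count alternatives stayed within 1.5 times the main count, and none of the named genes' calls reversed. Of 200 calls of named genes, 126 held in all alternatives other than the block. List members whose calls were lost without a library had been dropped first, so this share overstates how well calls hold.

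The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.455 to 0.47 (median 0.024, 13 of 45 above 0.1), and 7 of 18 libraries correlated best with their own number. With the number as a block, counts were 656, 456 and 3317 for hypoxia in the 3 genotypes, 32 and 1217 for the lines in normoxia, 31 and 140 in hypoxia, and 0 and 828 for the interactions.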

Other observations

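A few genes called in the same direction in all 3 genotypes are given here, chosen after their values were seen, with no test of a group and none of the difference in size between genotypes. Esm1, an endothelial proteoglycan gene, fell by 2.72 ± 0.26 in wild type, 1.59 ± 0.25 in β-arrestin 1 −/− and 2.09 ± 0.26 in the libraries labelled β-arrestin 2 −/−. Hilpda, a lipid droplet gene, fell by 1.64 ± 0.25, 0.98 ± 0.25 and 1.00 ± 0.25, and Stc1, a stanniocalcin gene, by 1.20 ± 0.25, 1.09 ± 0.25 and 1.51 ± 0.25, although both are known targets of hypoxia-inducible factors. On the fixed list of such targets and glycolysis genes 24 of 35 were above 0 in wild type. The Notch effector gene Hey2 rose by 1.00 ± 0.21, 1.36 ± 0.21 and 1.29 ± 0.21, the placental growth factor gene Pgf by 0.82 ± 0.17, 0.85 ± 0.17 and 0.84 ± 0.17, and Cd34 by 0.78 ± 0.12, 0.70 ± 0.12 and 0.35 ± 0.12. The calls of Stc1, Pgf, Hilpda and Cd34 were lost in at least 1 genotype without 1 library. With the tissue score as a covariate, Stc1, Hilpda, Hey2, Pgf and Cd34 were not called in wild type, nor Cd34 in the libraries labelled β-arrestin 2 −/−.

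The readings of the tests that follow were fixed after their results were seen, and the windows around the targeted genes were planned. Arrb2 was not lower in the libraries labelled β-arrestin 2 −/−. Wrong labels on libraries of the wild type stock were argued against: genes called alike in both exposures were more frequent within 10 Mb of Arrb2 than elsewhere (odds ratio 6.45, Fisher's exact p = 0.00494). A targeted allele that still gives fragments counted for Arrb2 stays open, with the gene at 125.9% of wild type in normoxia, because only a total per gene was deposited.

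In each line the same genes differed from wild type in both exposures. There were 5 higher and 9 lower in β-arrestin 1 −/−, Arrb1 included, where 0.011 and 0.0257 were expected of independent lists, and 17 and 16 in the other line, where 2.12 and 4.89 were expected and 15 went opposite ways. Loss of the arrestin acting on genes wherever they lie was argued against as the whole cause, since 11 of 13 genes (Arrb1 left out) and 32 of 33 lay within 10 Mb of another, where 10000 random sets had medians of 2 and 9 (p = 1e-04, the smallest p permutations can give). Pcdhb9 and Pcdhgb8 are given the same locus, and the Trim and H2 genes are families lying side by side. Random sets do not reproduce such families, so this p overstates the evidence. For the Trim genes, the sum of 7 family members was 58.8% of wild type in normoxia and 71.6% in hypoxia. Fragments moved only among these members would leave the sum unchanged, so this was argued against as the whole cause. The sum cannot show exchange within a pair, as between Trim34a, which fell, and Trim34b, which rose, so that stays open. DNA of another strain around the targeted gene may be a source, with window odds ratios of at least 18 and 1.93. Most normoxia calls of the second window were not called in hypoxia. A different H2 haplotype on chromosome 17 may be another source. H2-Ea-ps was between 115 and 265 CPM in 6 libraries and at most 0.183 in the other 12. Genes of this line called alike in both exposures numbered 8 in the 10 Mb from 20 Mb on that chromosome and 12 in the 10 Mb from 30 Mb. They thus also lay outside the H2 genes, Atp6v0c among them.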
